A study of Mus musculus with 5 samples.

How the data were processed

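Gastric corpus of Atp4b-DTR mice was dissociated with collagenase and trypsin, passed through a filter, and made into 10x Genomics 3′ single-cell libraries. There were 5 libraries from 3 mice per group: vehicle control, 36 h, 48 h and 72 h after the last of 3 daily doses of 225 ng diphtheria toxin, and 24 h after the last of 2 daily doses. Per the labels, the authors aligned reads to mm10 with Cell Ranger 6.0.0 and used Seurat 5, or Seurat 4 for the DT 2 days library. Per the file headers, the DT 2 days matrix was written by Cell Ranger 6.1.2. The deposited matrices hold raw UMI counts for 32285 genes, with no values changed by normalisation, and no barcode under 500 UMIs. How barcodes were called as cells and whether intronic reads were counted are not given in the sources used here. The deposited files held 15925, 14217, 12216, 11984 and 11026 barcodes for control, 36 h, 48 h, 72 h and DT 2 days. No cell annotation was held, so the authors' cell types were not used here.

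Barcodes were kept with at least 500 genes and 1000 UMIs (12875, 13144, 10701, 10595 and 10406) and at most 50% mitochondrial UMIs, which removed a further 489, 66, 80, 76 and 328. Doublets were scored with Scrublet as in scanpy 1.11.5. The highest-scoring cells were removed at a rate of 0.8% per 1000 barcodes, which took 2029, 1617, 1194, 1149 and 973 cells. Scrublet's own threshold would have taken 837, 970, 327, 265 and 185. All kept cells were clustered together from 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, seed 0), with no correction between libraries. Ratios were computed where both libraries had at least 50 cells of a class. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.

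Clusters were named from 20 marker sets fixed before the data were examined. The other choices made then were the 23 gene lists, the measures compared, the rule for named genes and most alternatives. The class whose markers had the highest mean z score was taken. Where its lead over the next class was under 0.5, the class with more of its markers among the 10 leading genes was taken. A score of at least 1.0 was needed, with at least 3 markers at 10 CPM and as many own markers among the 10 leading genes as any other class had. Clusters of shallow cells also needed a marker of their own class among the 10 leading genes. This rule is the last of 3 forms, and each form was revised after the class sizes per library had been seen. The first, with a minimum mean log2 fold of 0.75, left all chief cell clusters unnamed. The next asked for a marker among the leading genes in every cluster and left a histone-led cluster unnamed. Both were run as alternatives. Names are written as parietal-like and so on, since they rest on transcripts alone. Gastric epithelial cells are the parietal-, chief-, neck-, pit-, proliferating-, enteroendocrine- and tuft-like cells and the unnamed epithelial cells. Other classes found were squamous, macrophage or dendritic, B or plasma and mast cells, fibroblasts, smooth muscle and endothelium. Immune-like and stromal cells serve as measures of free RNA.

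UMIs were summed per class and library, and expression is given as CPM, the counts scaled by that sum. Ratios are log2 of CPM with a pseudocount of 1, each DT library over control. A gene was called higher or lower where its ratio passed 1.5 and the exact 95% Poisson interval of the ratio excluded 1. Printed intervals are of the ratio without the pseudocount. With 1 library per group they cover counting error only and say nothing of differences between mice. Lists were scored over members with at least 10 UMIs in the 2 libraries compared, as a median, its difference from the median of all genes, and its percentile among 10000 random lists drawn from the 200 genes nearest in expression. The interval of the acid secretion list median comes from Poisson redraws of its members' counts. Shares carry exact Clopper-Pearson 95% intervals, ratios of shares carry the log-method interval, and a count of 0 is given as the share that 3 counts would make. For shares of cells with a UMI, cells were thinned to 2000 UMIs, and cells below that depth were left out (156 of the control parietal-like cells, 35 at 36 h).

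The lists were acid secretion and parietal ion transport, estrogen-related receptors and coactivators, nuclear oxidative phosphorylation, mitochondrial-encoded genes, TCA cycle, fatty acid oxidation, glycolysis, mitochondrial biogenesis, S phase, G2/M phase, MYC targets and ribosome biogenesis, SPEM, mature chief cell, pit cell, immediate early, unfolded protein, p53 targets, interferon response, class II antigen presentation, inflammatory mediators, EGFR ligands and gland morphogens, hypoxia, and lysosome and autophagy. Of 401 list members 4 symbols did not match: Gif and Dpcr1 are present as Cblif and Mucl3, and Aldoa and Ddit3 each have more than 1 gene identifier. Beyond list members and markers, genes named are among the 10 highest and 10 lowest ratios in parietal-like cells, or the 5 highest and 5 lowest in other classes. They needed at least 50 CPM and 30 UMIs in 1 of the libraries compared. Mitochondrial, ribosomal protein, sex-linked, haemoglobin, immunoglobulin and predicted genes were left out of that ranking. Which of the ranked genes and list members were printed was chosen after their values were seen, with genes more abundant in stromal cells mostly left out. Values of 1 list member are not reported here.

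Alternatives were a mitochondrial limit of 25% or none, at least 2000 UMIs, no doublet removal, resolution 0.5 or 2, each library clustered alone, and putative female cells only (Xist and no Y-linked UMI). For expression they were TMM scaling, mitochondrial and the 20 most abundant genes left out of the total, and a pseudocount of 10. For lists and shares they were a ratio limit of 2, no thinning and at least 2 UMIs. Added after the data were seen were the earlier naming forms, clustering without the DT 2 days library, unnamed epithelial cells left out of the denominator, the reduced total for list members, and all alternatives for the chief-, neck-, pit-, enteroendocrine- and tuft-like shares. Comparisons within 1 cluster, and of proliferating-like cells without the histone-led cluster, were also added then. Clusters were formed from the same expression values, so comparisons within 1 cluster favour small differences by construction. Gene positions, intron lengths and exon lengths came from GENCODE vM21 (GRCm38).

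The method was tested on simulated data, with Poisson counts drawn from the control profile of parietal-like cells at the depths of control and 36 h. Of 9841 genes, sets of 50 were changed by 4-fold or 2-fold, up or down. The share called was 100% at 4-fold and 94.0% at 2-fold, and 0.05% of genes left alone were called. The intervals covered 95.4% of true ratios, and 3.7% of 300 random lists fell outside the middle 95%. The simulation held counting error alone, with no difference between mice or libraries and no shift of all genes. These rates therefore check the calculation and are not error rates for the comparisons of libraries made here.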

Results

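The series profiled single cells of the mouse gastric corpus, the acid-secreting region of the stomach, in Atp4b-DTR mice. Their parietal cells carry the receptor for diphtheria toxin (DT), so that the toxin removes them. There were 5 groups, each with 1 library from 3 mice: vehicle control, harvest at 36 h, 48 h and 72 h after the last of 3 daily doses of DT, and harvest 24 h after the last of 2 daily doses (named DT 2 days). The libraries held 250384659, 238005765, 223267598, 189671149 and 241870411 UMIs (unique molecular counts) in that order. After filtering, 10423, 11468, 9433, 9372 and 9121 cells were kept, with median depths of 9978, 13837, 17675, 15968.5 and 19575 UMIs per cell. With 1 library per group no test was made, and all intervals are 95% intervals of counting error only. The DT 2 days library came from another core facility and from female mice alone, so facility, number of doses and time cannot be told apart for it. Putative female cells alone give a view restricted by sex, but that choice needs an Xist UMI and so depends on depth. Cells with neither Xist nor Y-linked UMIs were 3216 of 10423 in control and 261 of 9121 in DT 2 days. Sex is therefore held only in part.

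The first question was which epithelial cells remained after the toxin. Parietal cells secrete acid, chief cells store pepsinogen, neck cells make mucin 6, pit cells line the surface with mucin 5AC, and dividing progenitors replace them. Cells named for proliferation genes were a larger share of the gastric epithelium in the 4 DT libraries than in control, and chief-like cells a smaller one. The first order held in every alternative run but 1, where the 72 h interval took in equal shares, and the other in each that named chief-like cells. Parietal-like cells were also a smaller share, but that order depended on how cells with much mitochondrial RNA were treated. Pit-like cells were a larger share, with 3 exceptions among the alternatives. The order of the neck-like share turned under 5 of the alternatives, so no direction is claimed for it.

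Parietal-like cells made up 22.7% of 8425 gastric epithelial cells in control. In the DT libraries they made up 16.1% at 36 h, 14.9% at 48 h, 19.3% at 72 h and 8.49% in DT 2 days. The ratios to control were 0.708 (0.665 to 0.755), 0.657 (0.614 to 0.703), 0.847 (0.797 to 0.899) and 0.373 (0.343 to 0.406). A mitochondrial limit of 25% in place of 50% left 541 of the 1916 control parietal-like cells and turned the order round at 36 h, 48 h and 72 h, with log2 ratios of 0.91, 0.83 and 1.19. At 72 h the order also turned without any mitochondrial limit (log2 0.16), at a clustering resolution of 2 (0.08) and with the unnamed epithelial cells left out of the denominator (0.25). The DT 2 days value went from −1.42 to −0.75 with each library clustered alone, and to −0.089 with the 25% mitochondrial limit. The parietal-like cells of control lay in 1 cluster with a median of 30.2% mitochondrial UMIs, those of 36 h and 48 h mainly in another with 7.0%, most of those of 72 h in a further one with 13.3%, and those of DT 2 days in their own with 9.4%.

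Proliferating-like cells were 4.45% of gastric epithelial cells in control, 16.4% at 36 h, 14.9% at 48 h, 8.80% at 72 h and 17.2% in DT 2 days. Their ratios to control were 3.69 (3.30 to 4.12), 3.34 (2.98 to 3.74), 1.98 (1.75 to 2.23) and 3.85 (3.45 to 4.31). The 72 h log2 ratio of 0.98 ranged from 0.17 in putative female cells (−0.13 to 0.47, no call) to 2.32 with at least 2000 UMIs per cell. The 48 h value of 1.74 was 0.88 in putative female cells and 2.54 with each library clustered alone. Chief-like cells were 31.8% in control and 9.62%, 6.91%, 5.601% and 8.74% in the DT libraries. Pit-like cells were 16.5% in control and 25.1%, 25.6%, 26.6% and 28.4%. Their log2 ratio turned to −0.16 at 36 h and −0.35 at 48 h without doublet removal, and to −0.86 at 72 h with resolution 0.5. Neck-like cells were 16.2% in control and 9.995%, 11.6%, 5.18% and 30.5%, with log2 ratios of −0.69, −0.48, −1.64 and 0.92. Without a mitochondrial limit the first 3 ratios were 0.27, 0.57 and 0.70. Without doublet removal the 48 h and 72 h ratios were 0.16 and 0.90, and resolution 2 gave 0.18 at 72 h. Resolution 0.5 gave 0.36 at 36 h, 0.70 at 48 h and −5.92 in DT 2 days, and libraries clustered alone gave 0.26 at 48 h. Epithelial clusters that met no naming rule held 1.42% of control cells, 14.8% at 36 h, 17.98% at 48 h, 30.0% at 72 h and 2.71% in DT 2 days, so shares of all named classes carry that open part.

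**Figure D1:**
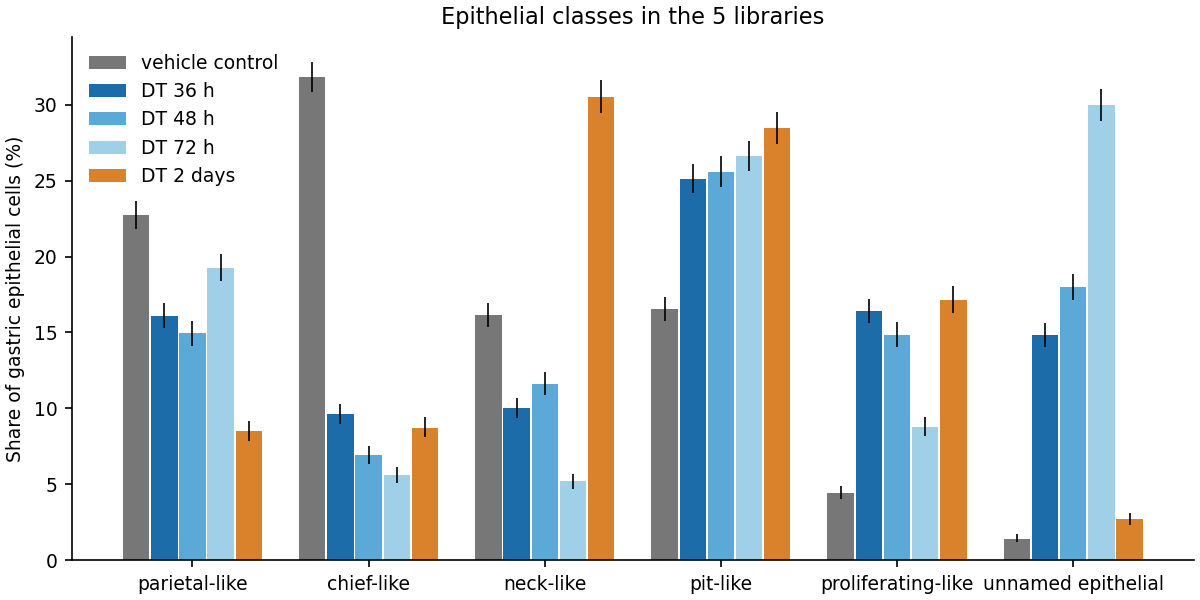
Share of gastric epithelial cells (percent, y axis) in each of 6 classes for the 5 libraries, with 95% Clopper-Pearson intervals as error bars. Proliferating-like cells stand at 4.45% in control and between 8.80% and 17.2% in the DT libraries, while unnamed epithelial cells reach 30.0% at 72 h.

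The second question was what the parietal-like cells of the DT libraries expressed. Atp4a and Atp4b encode the subunits of the acid pump, Kcnj16, Slc26a7, Slc26a9, Slc4a2 and Aqp4 carry ions and water, and Hrh2 and Sstr2 receive histamine and somatostatin. These were lower by over 1.5-fold than in control parietal-like cells in each DT library, apart from Aqp4 at 48 h and Slc4a2, Aqp4 and the acid pump at 72 h. The potassium channel subunits Kcne2 and Kcnq1 and the carbonic anhydrase Car2 were at or above the control level in CPM, apart from Kcne2 in DT 2 days, but relative to the shift of all genes Kcne2 lay below at 36 h and in DT 2 days, Kcnq1 at 36 h and 48 h and Car2 in DT 2 days. Genes of dividing cells, of ribosome building and of metaplasia, among them Mki67, Npm1, Clu and Dmbt1, were higher.

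Atp4a (ENSMUSG00000005553; GRCm38 chromosome 7, 30712209 to 30725534) stood at 13304 CPM (its UMIs scaled by the class total) in control. It was 4501 CPM at 36 h, 6854 at 48 h, 10647 at 72 h and 5513 in DT 2 days. Atp4b (ENSMUSG00000031449; GRCm38 chromosome 8, 13386205 to 13396825) stood at 10598 CPM in control and at 2092, 4497, 8333 and 2261 CPM. The log2 ratios at 36 h, with a pseudocount of 1 CPM, were −1.56 (−1.57 to −1.55) for Atp4a and −2.34 (−2.35 to −2.33) for Atp4b. Kcnj16 was 406 CPM in control and 30.1, 57.1, 112 and 131 in the DT libraries, and Slc26a7 was 56.8 against 0.38, 2.62, 1.69 and 4.90. Slc26a9 had log2 ratios of −2.19, −1.54, −0.79 and −1.21, and Aqp4 of −2.07, −0.52, −0.08 and −3.30. Hrh2 had −1.41, −1.13, −0.76 and −0.78, Sstr2 −2.05, −1.61, −1.55 and −2.18, and Slc4a2 −1.76, −0.67, −0.10 and −0.996. Kcne2 stood at 331 CPM in control (log2 0.07 at 36 h) and 346, 439, 479 and 291, Kcnq1 at 173 (log2 0.04 at 36 h) and 177, 203, 234 and 422, and Car2 at 1603 and 2306, 2419, 1894 and 1953.

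The median log2 ratio of all measured genes in parietal-like cells was itself 0.48 at 36 h, 0.32 at 48 h, 0.22 at 72 h and 0.75 in DT 2 days. Mitochondrial transcripts took 29.9% of this class's counts in control and 7.15%, 8.50%, 11.96% and 11.4% in the DT libraries. Relative to that shift, the median of the 24 acid secretion and parietal ion transport genes was −1.22, −0.79, −0.50 and −1.15. It lay below at least 99.9% of 10000 random lists matched on expression. At 36 h, 13 members were lower by over 1.5-fold and 2 were higher, and the numbers at 72 h were 8 and 2. The list shares 7 genes with the parietal markers that named the clusters, and the median log2 ratio of the other 17 was −0.70, −0.33, −0.25 and −0.12. Long genes were counted higher in other classes of the DT 2 days library, as given below, and are part of its all-gene median. List medians relative to all genes may therefore be too low in that library, here and in what follows.

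**Figure D2:**
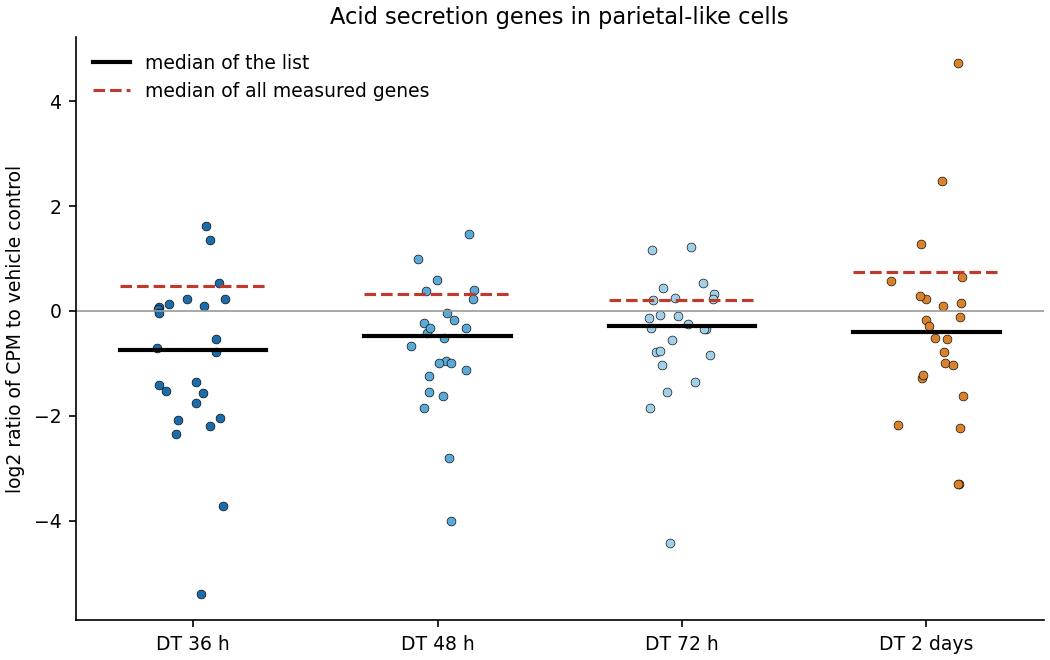
Log2 ratio to control (y axis) of each of the 24 acid secretion and parietal ion transport genes in parietal-like cells (points) for the 4 DT libraries, with the list median as a black line and the median of all genes as a red dashed line. The list median is −0.74 at 36 h and −0.28 at 72 h while that of all genes is 0.48 and 0.22.

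Transcripts encoded by the mitochondrial genome were also lower. All 13 mitochondrial-encoded genes were lower by over 1.5-fold in each DT library, with medians relative to all genes of −2.53, −2.18, −1.72 and −2.25, and mt-Co1 was 47540 CPM in control and 9529 at 36 h. The median share of mitochondrial UMIs in a parietal-like cell was 30.1% in control and 6.52%, 7.32%, 10.9% and 9.22% in the DT libraries. Relative to all genes, the 52 nuclear oxidative phosphorylation genes had medians of −0.96, −0.47, −0.16 and −1.37, and fatty acid oxidation genes −0.90, −0.52, −0.14 and −1.37. Without that reference the medians of these lists at 72 h, 0.06 and 0.08, turned negative under the other scalings. TCA cycle genes had relative medians of −0.66, −0.20, 0.00 and −1.02, and glycolysis genes −0.27, 0.18, 0.38 and −0.62. Mitochondrial biogenesis regulators stood at 0.35, 0.27, 0.06 and 0.15, with Tfam at 34.8 CPM in control and 63.0 at 36 h. The lipid genes Fabp3, Lpl and Apoa1 were low in all 4 DT libraries. Lpl was 1006 CPM in control and 25.7, 38.6, 179 and 47.8, and Apoa1 4716 and 166, 273, 1671 and 608. Hamp2 was 1089 CPM in control and 3.20 at 36 h, and Ttr was 607 CPM in control and 26.5 at 48 h. Angptl8 went the other way, from 0.57 CPM in control to 66.2, 79.5, 65.8 and 32.5.

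Dividing-cell transcripts were higher in these same cells. All 20 G2/M genes were higher by over 1.5-fold at 36 h, 48 h and in DT 2 days, and 19 at 72 h, with medians relative to all genes of 3.05, 2.08, 1.67 and 2.36. The 20 S phase genes had 1.93, 1.22, 0.76 and 1.68, and the 15 MYC target and ribosome biogenesis genes 1.79, 1.39, 1.10 and 1.13. Npm1 stood at 192 CPM in control and 1106, 987, 569 and 896 in the DT libraries, Ncl at 226 and 985, 789, 506 and 814, and Myc at 7.60 and 46.2, 22.0, 9.73 and 28.6. Mki67 was 1.47 CPM in control and 78.6, 33.8, 17.6 and 52.4, and stromal cells of the same libraries held 11.8 CPM and 41.1, 17.2, 28.6 and 19.7. At 72 h its level in parietal-like cells was thus below that of the stroma.

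At 2000 UMIs per cell, Mki67 or Top2a was found in 0.51% of parietal-like cells in control and in 16.0%, 7.68%, 5.13% and 11.8% in the DT libraries. Chief-like cells, which should lack both in the resting gland, showed 0.34% and 2.59%, 0.61%, 2.11% and 1.90%. Median depths were 9509 UMIs in control and 20415 at 36 h for parietal-like cells, and 43292.5 and 37590 for chief-like cells. Cycle genes were also higher in chief-like cells of the DT libraries, and whether through division or free RNA was not tested. This class is therefore a clear background in control alone. The parietal-like shares lay above the chief-like ones in each DT library, but no class gives a settled background there. Immune-like cells, which can themselves divide, showed 4.96% and 16.9%, 12.5%, 13.8% and 16.7%, as high as parietal-like cells or higher. With at least 2 UMIs required, the parietal-like shares were 0% in control (a count of 0 allows 0.17%) and 4.42%, 1.87%, 0.98% and 2.03%. Without thinning they were 2.04% and 50.0%, 35.5%, 22.2% and 42.5%.

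The 18 genes of spasmolytic polypeptide-expressing metaplasia (SPEM), a repair state of gland cells, had medians relative to all genes of 2.07, 1.26, 1.13 and 1.63 in parietal-like cells. Dmbt1 was 1.36 CPM in control and 199, 68.0, 38.5 and 146 in the DT libraries, Pigr 1.19 and 138, 44.8, 110.4 and 66.4, and Wfdc2 1.36 and 102, 54.8, 37.2 and 76.2. Clu was 77.9 and 1356, 478, 305 and 1185, with 70.9 to 264 CPM in stromal cells. Muc6 was higher at 36 h (log2 1.74) and lower at 72 h (−1.19). Mature chief cell genes had relative medians of 0.75, −0.25, −0.09 and −1.22, and pit cell genes −0.60, −0.46, 0.08 and −0.01. Immediate early and dissociation genes, which tissue handling can induce, stood at 1.59, 1.04, 0.67 and 1.39, with Atf3 at 163 CPM in control and 1461 at 36 h. Unfolded protein and integrated stress response genes had 0.11, 0.16, 0.23 and −0.17, p53 targets 0.04, 0.11, 0.16 and −0.03, and inflammatory mediators and alarmins 0.32, 0.54, 0.75 and 1.20. Relative medians were −1.03, −0.49, −0.62 and −0.57 for hypoxia and angiogenic signals, with Car9 at 42.0 CPM in control and 15.3 at 36 h. They were 0.05, −0.10, −0.40 and −0.08 for EGFR ligands and gland morphogens, and −0.41, −0.29, −0.01 and −0.43 for lysosome and autophagy genes.

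The third question concerned Esrrg, which encodes an estrogen-related receptor that drives mitochondrial and ion transport genes in parietal cells, and its coactivator Ppargc1a. In parietal-like cells Esrrg was near or above the control level in CPM while the acid pump was lower. It was higher in proliferating-like cells of the DT libraries than in those of control, but less so within the clusters shared with control, and in 1 of them not at 72 h. Ppargc1a was higher in both classes, and Perm1, another gene of this axis, was lower in parietal-like cells. Esrrg is a long gene, and its DT 2 days values may carry the higher counts of long genes in that library, which were not measured in parietal-like cells. Whether those of Ppargc1a and Kcnq1 do so too was not tested.

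Esrrg (ENSMUSG00000026610; GRCm38 chromosome 1, 187608791 to 188214885) was 304 CPM in control parietal-like cells and 476, 361, 298 and 2077 CPM in the DT libraries. Its log2 ratios were 0.65 (0.60 to 0.69), 0.25 (0.20 to 0.30), −0.03 (−0.08 to 0.02) and 2.77 (2.73 to 2.81). With TMM scaling these became 0.05, −0.13, −0.25 and 1.94, and with mitochondrial and the 20 most abundant genes left out of the total 0.22, −0.18, −0.38 and 2.31, so the 48 h direction depends on the scaling. Ppargc1a was 119 CPM in control and 206, 197, 181 and 774, Esrra 63.7 and 88.8, 105, 102 and 100.2, and Perm1 17.0 and 1.17, 3.88, 5.86 and 3.06. The 9 estrogen-related receptor and coactivator genes together had medians relative to all genes of −0.34, −0.62, −0.54 and −0.10. At 2000 UMIs per cell, 40.7% of control parietal-like cells held an Esrrg UMI, and 55.4%, 47.7%, 41.5% and 83.3% of those in the DT libraries.

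In proliferating-like cells Esrrg was 14.1 CPM in control and 126, 90.4, 66.4 and 448 CPM in the DT libraries, with log2 ratios of 3.07, 2.60, 2.16 and 4.89. At 2000 UMIs per cell, 3.22% (1.67 to 5.55) of control proliferating-like cells held an Esrrg UMI, against 16.6% (14.6 to 18.7), 13.0% (11.1 to 15.1), 9.67% (7.54 to 12.2) and 36.5% (33.8 to 39.2). In immune-like cells the background share was 1.42% and 1.88%, 2.31%, 1.32% and 3.03%, the last below the share that 3 counts would make. Median depths were 20270 UMIs in control and 25022 at 36 h for proliferating-like cells, and 3213 and 5892 for immune-like cells. One of the clusters was led by histone genes and had parietal as its second class. It held 3, 326, 179, 112 and 3 of the proliferating-like cells from control to DT 2 days. With it left unnamed the log2 ratios for Esrrg were 1.81, 1.44 and 0.56 at 36 h, 48 h and 72 h. The other 2 clusters with control cells gave 1.32, 0.73 and −0.05 (162 control cells, the first) and 1.86, 1.95 and 1.17 (210 control cells, the second). In putative female cells alone the 48 h value was 1.56, and with at least 2000 UMIs per cell the 72 h value was 1.48.

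Proliferating-like cells also differed in the lineage genes they carried. The parietal genes Atp4a, Kcnq1 and Kcne2 and the metaplasia genes Dmbt1 and Pigr were higher in the DT libraries, and the pit cell genes Muc5ac and Gkn2 were lower. At 36 h, 48 h and 72 h, most of the Atp4a excess and all of that of the acid secretion list came from the histone-led cluster. Of the 2 other clusters shared with control, the second held most of the fall in Gkn2 and the pit cell list, and the first showed little of it. Outside the histone-led cluster, the Atp4a rise at 36 h and 48 h was confined to 1 cluster. Of the 1241 such cells in DT 2 days, 1219 lay in a cluster of their own. Ppargc1a was 2.23 CPM in control and 40.8, 20.3, 16.4 and 72.1, Kcnq1 5.70 and 80.0, 60.0, 47.8 and 153, and Kcne2 6.45 and 60.2, 55.8, 53.6 and 30.6. Atp4a was 77.1 CPM in control, below the 228 CPM of control stromal cells, and 756, 716, 670.1 and 238 CPM in the DT libraries, where stromal cells held 49.9, 49.9, 143 and 28.2. Relative to all genes, the acid secretion list had medians of 0.30, 0.32, 0.42 and −0.13 and oxidative phosphorylation genes 0.30, 0.46, 0.45 and −0.09. The SPEM genes had 0.79, 0.75, 0.94 and 0.57, with Pigr at 6.07 CPM in control and 183 at 36 h. Pit cell genes stood at −1.54, −1.50, −1.11 and −1.13, and Muc5ac was 2468 CPM in control and 147, 103, 79.0 and 640.1. Interferon response genes had a relative median of 2.52 at 72 h.

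Without the histone-led cluster, Atp4a was 69.4 CPM in control and 184, 118, 126 and 235 in the DT libraries, and Atp4b was 65.8 and 24.8, 18.5, 54.7 and 63.2. Kcnq1 was 5.11 CPM in control and 47.7, 32.0, 25.5 and 153, Kcne2 5.73 and 18.7, 12.6, 10.1 and 30.6, and Ppargc1a 2.12 and 14.7, 8.73, 8.32 and 72.2. In the first of the 2 shared clusters Atp4a was 86.1 CPM in control and 294, 164 and 160 at 36 h, 48 h and 72 h, and in the second 60.1 and 53.3, 47.4 and 90.1. Kcne2 was 12.9 CPM and 30.2, 19.4 and 13.7 in the first, and 1.74 and 4.98, 2.03 and 6.13 in the second. Gkn2 was 244 CPM in control and 201, 184 and 153 in the first, and 36392 and 9567, 13916 and 8187 in the second. Pit cell genes relative to all genes had medians of −0.31, −0.25 and −0.28 in the first and −1.10, −0.96 and −0.86 in the second. Muc5ac stayed lower in both, at 447 CPM and 19.8, 10.1 and 5.23 in the first and 3603 and 394, 309 and 192 in the second. Relative to all genes the acid secretion list without the histone-led cluster had medians of −0.07, −0.17, −0.18 and −0.13. Oxidative phosphorylation genes had 0.21, 0.31, 0.36 and −0.09, and SPEM genes 1.02, 0.77, 0.93 and 0.56. Pigr was 6.1 CPM in control and 207, 159, 211 and 138, Dmbt1 49.3 and 493, 364, 307 and 384, and Muc5ac 2480 and 191, 127, 94.6 and 641.

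At 2000 UMIs per cell, Atp4a or Atp4b was found in 21.2% (17.1 to 25.7) of control proliferating-like cells and in 36.9% (34.3 to 39.6), 27.6% (24.9 to 30.3), 34.4% (30.8 to 38.1) and 17.8% (15.7 to 20.03) of those in the DT libraries. Immune-like cells, which should lack both but are shallow, showed 59.6% in control and 10.0%, 13.4%, 32.2% and 4.55%. Among deeper classes, pit-like cells showed 21.8% and 8.48%, 6.85%, 21.4% and 3.56%, and chief-like cells 28.0% and 29.1%, 22.8%, 37.0% and 13.9%. The control share therefore reads as background, and the 72 h share lay between pit-like and chief-like cells. With at least 2 UMIs, proliferating-like cells showed 2.14% in control and 25.8%, 19.3%, 18.9% and 10.3%. Pit-like cells showed 3.70% and 1.17%, 0.43%, 3.81% and 0.19%, chief-like cells 8.26% and 13.1%, 7.72%, 12.2% and 3.80%, and immune-like cells 22.0% and 1.25%, 1.39%, 6.58% and 0% (a count of 0 allows 4.55%). Without thinning the order turned at 36 h and 48 h, with 89.9% in control and 74.1% and 71.5%. All these proliferating-like shares include the histone-led cluster, which held 3 of 375 such cells in control. It held 326 of 1349 at 36 h, 179 of 1088 at 48 h and 112 of 674 at 72 h. Shares without it were not computed, so how far the other proliferating-like cells of these libraries held pump transcripts stays open.

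**Figure D3:**
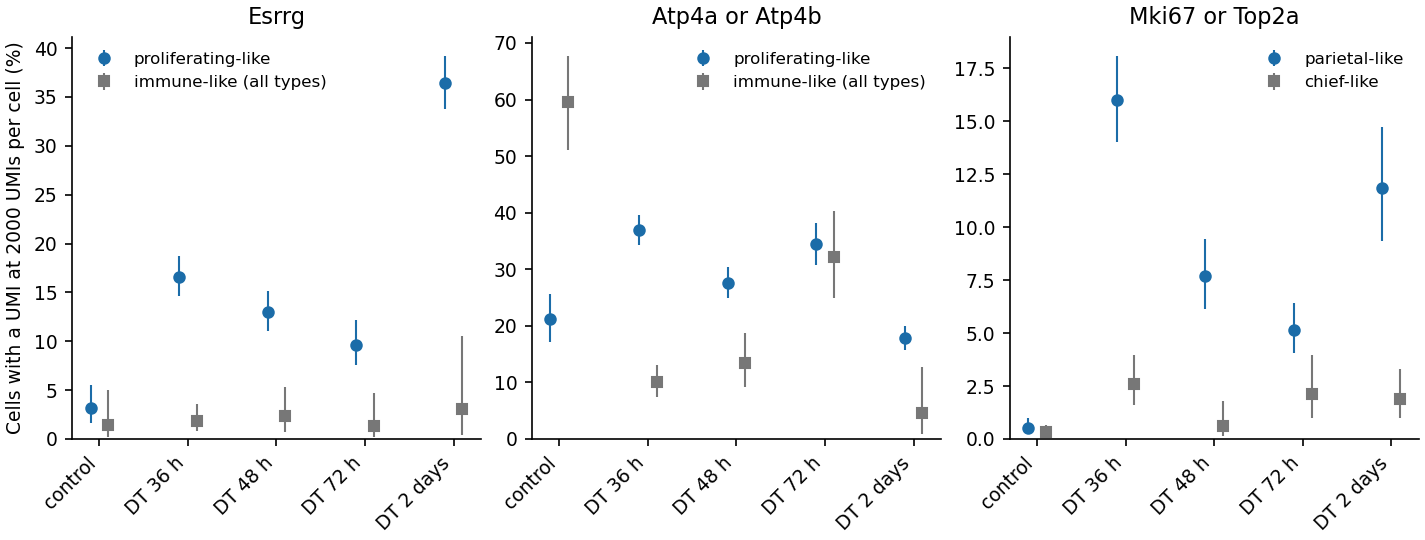
Percent of cells (y axis) with at least 1 UMI at 2000 UMIs per cell in the 5 libraries, with 95% Clopper-Pearson intervals, for Esrrg and for Atp4a or Atp4b in proliferating-like and immune-like cells and for Mki67 or Top2a in parietal-like and chief-like cells. Esrrg is in 3.22% of control proliferating-like cells and in 9.67% to 36.5% of those in the DT libraries, while immune-like cells hold 1.32% to 3.03%. Esrrg is a long gene, and its DT 2 days share carries the higher counts of long genes in that library. Proliferating-like cells here include the histone-led cluster.

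In chief-like cells metaplasia genes were higher. Pgc and Cblif, which encode pepsinogen C and intrinsic factor, stayed near control in CPM but lay below the shift of all genes in each DT library. The digestive enzyme gene Try10 was lower. CPM in this class depends on a few abundant genes. Without mitochondrial and the 20 most abundant genes, 0.124 of the total was left in control and 0.228, 0.209, 0.269 and 0.219 in the DT libraries. Single genes of this class are not given under other scalings. Pla2g1b was lower by over 1.5-fold at 48 h and 72 h alone. Pigr, Dmbt1, Reg3g, Gkn3, Clu and Sox9 were higher in all 4 DT libraries. Psca was lower. The median log2 ratio of all genes was 0.63, 0.47, 0.69 and 0.66 in this class. Relative to it, SPEM genes had medians of 1.18, 1.23, 1.45 and 1.78 and mature chief cell genes −0.65, −0.57, −0.86 and −0.88. Pgc was 157978 CPM in control and 147563, 157496, 143059 and 186276, and Cblif 3774 and 4203, 3477, 4203 and 4109. Try10 was 331 CPM in control and 116, 104, 145 and 173, and Pla2g1b 245243 and 173738, 160971, 152848 and 206853. Pigr was 1.09 CPM in control and 216, 183, 320.3 and 424, Gkn3 7.64 and 466, 596, 899 and 268, Reg3g 0.32 and 114, 79.4, 130.4 and 229, and Clu 137 and 2555, 2133, 1898 and 4681. Sox9 was 18.1 CPM in control and 67.0, 58.0, 56.9 and 69.4. Psca was 7155 CPM in control and 2787, 2547, 2628 and 2561. All 20 S phase genes were higher by over 1.5-fold in each DT library, with relative medians of 0.99, 0.93, 0.85 and 1.05. Unfolded protein genes stood at −0.56, −0.44, −0.38 and −1.74. Creld2 was 57.0 CPM in control and 10.7 in DT 2 days, and Sdf2l1 97.9 and 19.3.

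Of 2682 control chief-like cells, 2356 lay in 1 cluster, and 690, 451 and 412 of those of 36 h, 48 h and 72 h lay in another. That other cluster also held 326 control cells. Within it, Pigr was 6.72 CPM in control and 251, 207 and 342 in those 3 libraries, Dmbt1 2.02 and 167, 117 and 59.4, and Reg3g 3.36 and 134, 91.8 and 139. Gkn3 was 69.9 CPM and 545, 691 and 967, and Clu 501 and 2917, 2337 and 1993. Sox9 was 58.5 CPM in these control cells and 75.2, 63.3 and 59.9, so little of its difference was left. Psca was 3853 CPM and 2390, 2150 and 2483, and Pla2g1b 168485 and 167634, 156958 and 149336. Relative to all genes SPEM genes had medians of 0.83, 0.81 and 1.34, S phase genes 1.48, 1.23 and 1.19 and mature chief cell genes −0.10, −0.02 and 0.09. Mature chief cell genes were thus not lower within this cluster, though grouping cells by these same expression values favours small differences within it.

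In the main control cluster, which held 97 chief-like cells of 36 h and 54 of 48 h, the differences were mostly smaller. Relative to all genes, SPEM genes had medians of 0.41 and 0.35 there and S phase genes 0.19 and 0.40. Dmbt1 was 0.44 CPM in control and 6.92 and 10.2, Reg3g 0.25 and 4.15 and 5.75, Pigr 0.95 and 30.1 and 35.1, and Clu 128 and 609 and 911. The 595 chief-like cells of DT 2 days in their own cluster have no such comparison.

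Neck-like cells had less of the neck marker Muc6 and of the chief cell genes Pga5 and Pgc, and more cycle and metaplasia transcripts. Dmbt1, Pigr and Cftr were higher, and Cftr is itself a neck marker, so the neck markers did not move together. Sox9 was lower by over 1.5-fold at 72 h and in DT 2 days alone. Muc6 was 5715 CPM in control and 1142, 1652, 1050 and 924, Pga5 2225 and 105, 143, 77.1 and 183, and Pgc 151013 and 40777, 49856, 50612 and 33422. Dmbt1 was 8.85 CPM in control and 338, 253, 148 and 538, Pigr 42.9 and 468, 409, 374 and 442, Cftr 1.56 and 23.1, 23.7, 24.7 and 75.2, and Sox9 440 and 294, 346, 217 and 259. The median log2 ratio of all genes was 0.14, 0.01, −0.04 and 0.43. Relative to it, G2/M genes had medians of 2.22, 1.79, 2.07 and 2.74, S phase genes 1.59, 0.83, 1.05 and 1.43, and SPEM genes 1.04, 1.11, 0.89 and 0.75. The SPEM list shares 5 genes with the neck markers, and the median log2 ratio of the others was 1.60, 1.43, 1.15 and 1.31. Mki67 was 6.16 CPM in control and 60.7, 37.8, 47.1 and 80.8. Neck-like cells lay largely in separate clusters for control, for the 3 later harvests together and for DT 2 days.

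Pit-like cells differed most in interferon and antigen presentation genes at 72 h. Isg15, Irf7 and Ifit1 respond to interferon, and H2-Aa and Cd74 serve class II antigen presentation. These genes were highest at 72 h in this class, and in parietal-, chief-, neck- and proliferating-like cells the median of the interferon list was highest at 72 h too. Muc5ac, which marks pit cells, was lower in all 4 DT libraries, and Gkn1 was lower by over 1.5-fold at 36 h and 48 h. Clca1 and Pigr were higher. Isg15 was 7.72 CPM in control and 30.5, 36.6, 272 and 18.5 in pit-like cells, and Irf7 8.02 and 24.2, 28.1, 160 and 6.72. Cd74 was 5.25 CPM in control and 21.1, 9.04, 490 and 1.93, and H2-Aa 0.91 and 3.84, 1.65, 88.9 and 0.39. Relative to all genes, whose median log2 ratio was 0.05, −0.04, −0.11 and 0.22, interferon genes had medians of 1.51, 1.59, 4.36 and 0.23 in this class. Class II genes had 1.26, 0.36, 5.55 and −0.90. At 36 h the excess lay mainly in 250 pit-like cells with Xist and no Y-linked UMI, whose interferon and class II medians were 3.24 and 2.66 over the same cells of control. The 1250 cells with Y-linked UMIs only had 0.88 and 0.65. In the main control cluster, with 98 pit-like cells of 36 h and 114 of 48 h, the relative interferon medians were 1.29 and 0.61 and the class II medians −0.19 and 0.28. In parietal-like cells the interferon medians were 0.47, 0.91, 3.01 and 0.26 and the class II medians 0.81, 0.42, 3.34 and −0.49. S phase genes were lower in pit-like cells, with −0.21, −0.75, −0.55 and −0.55. Clca1 was 4.03 CPM in control and 213, 559, 158 and 133, and Muc5ac 3728 and 1345, 748, 672 and 2150. Gkn1 was 52447 CPM in control and 32349, 29599, 35931 and 40512. Sprr2a3 was 438 CPM in control and 4697 at 48 h. These pit-like cells lay in different clusters, with 1352 control cells in 1, 1724 and 1608 of 36 h and 48 h in another, 1351 of 72 h in a further one and 2034 of DT 2 days in their own.

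**Figure D4:**
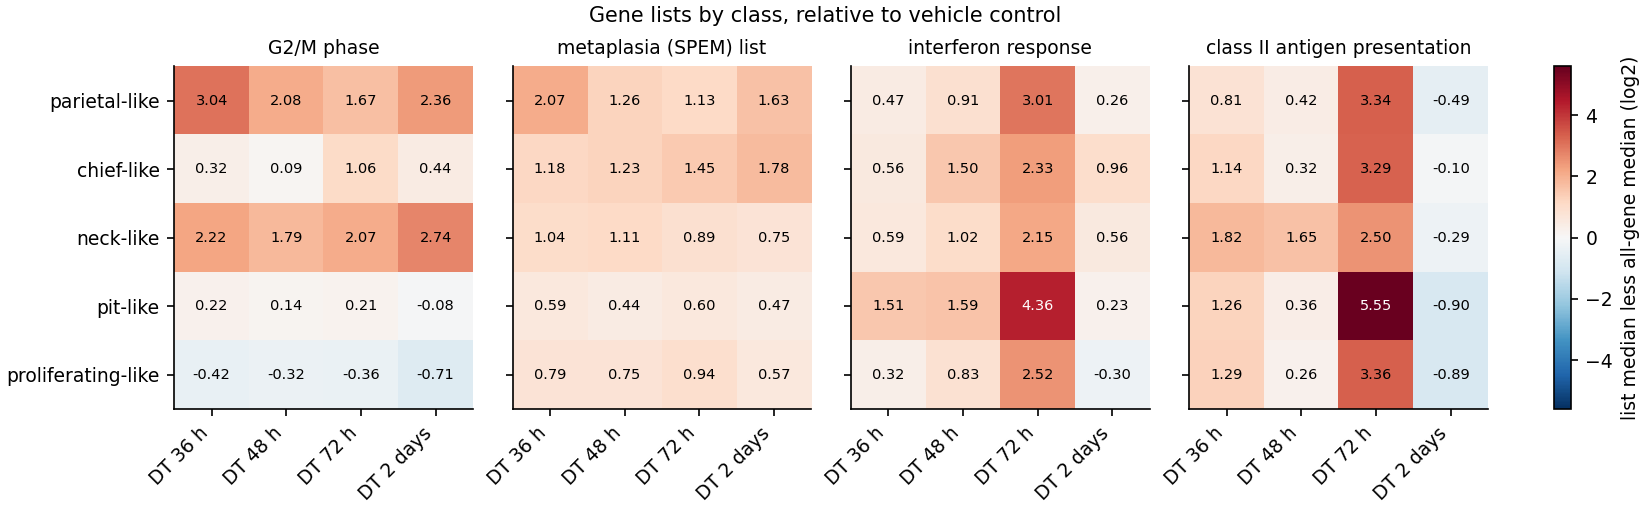
Heat maps of list medians (log2 ratio to control less the median of all genes) for G2/M, SPEM, interferon response and class II antigen presentation genes, with the 4 DT libraries on the x axis and 5 classes of cells on the y axis. Interferon values at 72 h run from 2.15 in neck-like to 4.36 in pit-like cells, and class II values reach 5.55 in pit-like cells.

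Over all 23 lists and 5 classes, list members were higher by over 1.5-fold in 838, 698, 780 and 787 cases at 36 h, 48 h, 72 h and in DT 2 days, and lower in 181, 185, 167 and 253. These calls are not relative to the shift of all genes. That shift itself passed 1.5-fold in chief-like cells at 36 h, 72 h and in DT 2 days, and in parietal-like cells of DT 2 days. No share over all genes is given, so the excess of higher over lower members is not read as a result about the lists. With TMM scaling the DT 2 days numbers were 505 higher and 501 lower, and the 36 h number lower was 299. With mitochondrial and the 20 most abundant genes left out of the total, 291, 305, 287 and 407 were lower. In the DT 2 days library, genes with the most intron sequence were higher than genes with the least, by 0.84 (chief-like) to 1.34 (stromal) log2 against the 48 h library. The trend was not measured in parietal-like cells. Values for long genes in that library, such as Camk1d at 0.06 CPM in control and 840 in parietal-like cells, and Esrrg itself, may carry it. The median of all genes in that library includes them, so list medians relative to it may be too low there. The genes lower in its parietal-like cells included Ifi27, at 658 CPM in control and 50.0, and Aqp4.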

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

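Both tests of free RNA for acinar genes, all tests of these genes at 36 h and the added criterion for the sex of the mice were chosen only after the results were seen.

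Neck-like cells stood out because the DT libraries went opposite ways in the planned analysis. Their share over control was 0.618 at 36 h, 0.719 at 48 h and 0.321 at 72 h, and 1.889 in DT 2 days. This difference between libraries was not tested, and the facility and the doses also differ. The direction turned under 5 of the alternatives tried, among them no mitochondrial limit with 0.267, 0.567 and 0.701 (log2) at 36 h, 48 h and 72 h, so it is not taken as a result. Squamous-like cells were 4.583% of the cells kept in DT 2 days (418 cells), with 4 cells in control, in a class that no comparison used. Acinar pancreas genes also stood out, with 2607.4 CPM in unnamed epithelial cells at 36 h and 2127.7 CPM at 72 h, against 0.6 CPM in control.

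Long genes were higher in the DT 2 days library. This was measured in pit-, neck-, chief- and proliferating-like cells and in stromal cells, and not in parietal-like cells. In the fifth of genes with the most intron sequence, the median log2 ratio to the 48 h library lay at least 0.838 above that of the fifth with the least, in each of these 5 classes, and 1.337 above it in stromal cells. Counting of unspliced RNA in that library may explain this, and the limit set beforehand was met. Intronic reads were not measured, and any cause that raises genes with much intron sequence would meet that limit. Sex does not explain the trend, since female and male cells of the 48 h library differed by at most 0.054. Exon length gave 0.253 at most, too little to explain the trend and above the 0.2 set to exclude it. Whether the facility, the software version or nuclear RNA lies behind it stays open, and no biological explanation was tested.

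Interferon and class II genes were higher in pit-like cells at 72 h. The limit set beforehand against RNA or doublets from immune cells was met, with macrophage markers at a median log2 ratio of 0.656 and class II genes at 5.437. This speaks of macrophages alone, and macrophage or dendritic cells numbered 149 in control and 146 at 72 h. An unnamed cluster led by class II genes held 5 cells in control, 92 at 36 h, 56 at 48 h, 78 at 72 h and 51 in DT 2 days. It was thus not largest at 72 h. Markers of other immune cells were not tested, so RNA or doublets from those cells stay open. The limit written beforehand for the sex of the mice was met, with the interferon median 1.181 higher in 757 cells with Xist only than in 772 cells with Y-linked UMIs only. That limit did not ask the other sex to be near control, and cells with Y-linked UMIs only stood 3.318 above their control counterparts, so sex is excluded as the whole cause but may add to it. At 36 h the same split was wider, with 3.244 over control in cells with Xist only and 0.878 in cells with Y-linked UMIs only, while at 48 h the first lay 0.762 below the second. A response to time after injury and a difference between the mice used remain open, since each group had 1 library.

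Acinar pancreas genes at 72 h were set against 2 sources, with a gene list chosen after such genes were seen leading a cluster. Free RNA alone would give like counts in every class, and the highest, the unnamed epithelial cells, held 12.84 times the UMIs per cell of the lowest at 72 h. Among named classes that ratio was 2.49, so free RNA may explain their counts. A few acinar cells within the unnamed clusters may be the source, since 1 in 100 of these cells carried 74.0% of the list's UMIs at 72 h, but whether they came from adjoining pancreas was not tested. Ctrb1 and Prss2 stood at 817 and 433 CPM in unnamed epithelial cells at 72 h, while in control the list had 873.7 CPM in enteroendocrine-like cells, so the stomach expresses part of it.

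At 36 h, where the same tests were run on these acinar genes, the unnamed epithelial cells held 72.02 times the UMIs per cell of the lowest class, so free RNA alone is again excluded. A few acinar cells may be the source there too, since 1 in 100 of the unnamed epithelial cells carried 98.1% of the UMIs. Among named classes the highest, enteroendocrine-like cells, held 5.92 times the lowest, but in control these cells carried 5.91 UMIs of the list each, so they say nothing of free RNA. They were left out once this was seen, and among the other named classes the ratio was 1.84, so free RNA may explain their counts.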

How the results depend on the processing

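Among the alternatives given here, those chosen only after the data were seen were the earlier forms of the naming rule, clustering without the DT 2 days library, leaving unnamed cells out of the denominator, the reduced total for list members, and every alternative for the chief-, neck-, pit-, enteroendocrine- and tuft-like shares. No paired analysis was possible because each group has 1 library and no replicate is shared between groups. Values are log2 ratios to control unless a percent or a count is named, and the cause of a shift was not tested unless it is stated.

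The parietal-like share (−0.50, −0.61, −0.24 and −1.42 at 36 h, 48 h, 72 h and in DT 2 days) stayed within its counting interval in 24 of 47 alternatives, moved in 17 and reversed in 6. A mitochondrial limit of 25% gave 0.914, 0.833, 1.189 and −0.089. By its construction it removed most control cells of this class, since their median mitochondrial share was 30.1%. No mitochondrial limit gave −0.216, −0.336 and 0.156 at 36 h, 48 h and 72 h. Resolution 2 gave −0.248, −0.303, 0.078 and −1.106. Each library clustered alone gave −0.098, −0.427, −0.117 and −0.754. Unnamed cells left out of the denominator gave −0.286, −0.341 and 0.254. Putative female cells gave −0.978 at 36 h, −0.62 at 72 h and −1.298 in DT 2 days. No doublet removal gave −0.082 at 72 h, and clustering without the DT 2 days library −0.647 at 36 h.

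The proliferating-like share (1.88, 1.74, 0.98 and 1.95) kept its sign in all 47 alternatives and moved beyond its interval in 23. A mitochondrial limit of 25% gave 1.616, 1.492 and 0.415 at 36 h, 48 h and 72 h. Each library clustered alone gave 2.11, 2.536 and 2.178. The naming rule that asks for a marker in every cluster gave 1.494, 1.491 and 0.733. Clustering without the DT 2 days library gave 2.096, 1.97 and 1.797, and unnamed cells left out of the denominator 2.093, 2.004 and 1.477. Putative female cells gave 0.875 at 48 h, 0.172 at 72 h (−0.13 to 0.474, so no call) and 1.55 in DT 2 days. No doublet removal gave 1.721 at 36 h and 0.795 at 72 h. At 72 h, no mitochondrial limit gave 1.648, at least 2000 UMIs 2.316, and resolution 2 gave 1.808.

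The neck-like share (−0.69, −0.48, −1.64 and 0.92) reversed in 10 of 47 alternatives and moved in 21. No mitochondrial limit gave 0.267, 0.567 and 0.701 at 36 h, 48 h and 72 h. No doublet removal gave 0.159 at 48 h and 0.895 at 72 h, resolution 2 gave 0.176 at 72 h, and libraries clustered alone gave 0.261 at 48 h. Resolution 0.5 gave 0.36, 0.702 and −5.919 at 36 h, 48 h and in DT 2 days, where 21 cells were left. Putative female cells gave −3.357 at 72 h and 0.873 in DT 2 days. The pit-like share (0.61, 0.63, 0.69 and 0.78) reversed in 3 of 47, with −0.164 at 36 h and −0.351 at 48 h without doublet removal and −0.861 at 72 h with resolution 0.5. Chief-like shares stayed lower in all 43 alternatives, from −0.96 in DT 2 days to −3.807 at 72 h, and the first naming form gave no such cells. No reversal was found for enteroendocrine- and tuft-like shares.

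The acid secretion list in parietal-like cells (−0.74, −0.47, −0.28 and −0.40) stayed negative in all 59 alternatives, within its interval in 35. TMM scaling gave −1.335, −0.841, −0.505 and −1.23, and the reduced total −1.171, −0.901, −0.626 and −0.864. Both remove the shift of all genes by construction. Putative female cells gave −0.938, −0.398, −0.472 and −0.456. At 36 h, the 25% limit gave −0.645, no mitochondrial limit −0.808, no doublet removal −0.609, libraries clustered alone −0.775, clustering without DT 2 days −0.704 and a pseudocount of 10 CPM −0.619. At 48 h that pseudocount gave −0.398. At 72 h, no mitochondrial limit gave −0.358 and resolution 2 gave −0.356. In DT 2 days, no doublet removal gave −0.331, resolution 2 gave −0.477 and libraries clustered alone −0.529.

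Esrrg in parietal-like cells (0.65, 0.25, −0.03 and 2.77) stayed within its interval in 23 of 51 alternatives, moved in 26 and reversed in 2, both scalings at 48 h. TMM gave 0.052, −0.126, −0.254 and 1.938, and the reduced total 0.217, −0.183, −0.375 and 2.306. The 25% limit gave 0.552, 0.144, −0.133 and 2.67, no mitochondrial limit 0.579, 0.189, −0.101 and 2.893, and no doublet removal 0.774, 0.436, 0.141 and 2.973. Resolution 2 gave 0.186 at 48 h, −0.1 at 72 h and 2.697 in DT 2 days. Libraries clustered alone gave 0.573 at 36 h, −0.1 at 72 h and 2.618 in DT 2 days. Putative female cells gave 0.028 at 72 h, and clustering without DT 2 days 0.723 at 36 h. At 72 h the main value has an interval that holds 0, so its sign is not a call.

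Esrrg in proliferating-like cells (3.07, 2.60, 2.16 and 4.89) stayed higher in all 51 alternatives, within its interval in 38. The naming rule that asks for a marker in every cluster gave 1.806, 1.441 and 0.563 at 36 h, 48 h and 72 h. Putative female cells gave 1.556 at 48 h, 2.663 at 72 h and 4.696 in DT 2 days. At 72 h, no mitochondrial limit gave 1.767, at least 2000 UMIs 1.48, resolution 2 gave 1.766, libraries clustered alone 1.696 and clustering without DT 2 days 1.676. In DT 2 days, libraries clustered alone gave 4.485 and TMM 4.589.

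Shares of cells with a UMI follow depth by construction. Atp4a or Atp4b in proliferating-like cells was 89.87%, 74.05%, 71.51%, 91.25% and 51.57% from control to DT 2 days without thinning and 2.14%, 25.77%, 19.26%, 18.9% and 10.27% with at least 2 UMIs. Mki67 or Top2a in parietal-like cells was 2.04%, 50.04%, 35.47%, 22.24% and 42.51% without thinning and 0%, 4.42%, 1.87%, 0.98% and 2.03% with at least 2 UMIs. List members called higher numbered 511 at 36 h and 373 at 48 h with a ratio limit of 2, and 505 in DT 2 days with TMM. Members called lower numbered 98, 96, 83 and 116 with a ratio limit of 2, 299 at 36 h and 501 in DT 2 days with TMM, and 291, 305, 287 and 407 with the reduced total. Clustering without the DT 2 days library gives no value for that library.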

Other observations

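No value here had a test, and all were chosen for this part after they were seen.

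Tuft-like cells were 0.629% of gastric epithelial cells in control, 1.51% at 36 h, 1.69% at 48 h, 0.836% at 72 h and 0.539% in DT 2 days. Their ratios to control were 2.40 (1.74 to 3.30), 2.69 (1.95 to 3.71), 1.33 (0.924 to 1.91) and 0.857. Enteroendocrine-like cells were 6.23% in control and 6.41%, 6.40%, 3.71% and 3.39%. Of all cells kept, macrophage or dendritic cells were 1.43% in control and 3.76%, 1.69%, 1.56% and 0.691%. Fibroblasts were 5.10% and 8.26%, 5.63%, 5.74% and 3.43%, and B or plasma cells 0.058% and 0.41%, 0.901%, 0.224% and 0.022%. Mast cells were not found in control, where a count of 0 allows 0.029%, and were 0.235% at 36 h.

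Clca1, Chil4 and Sprr2a3 in pit-like cells were highest at 48 h among the 5 libraries. Chil4 was 1.95 CPM in control and 130.4 CPM at 48 h. The unnamed epithelial cells of 36 h and 48 h lay mainly in a cluster of 1027 and 1246 cells led by Dmbt1 and Tff2. Those of 72 h lay mainly in another of 2040 cells led by acinar genes. Most of its cells need not express these genes, since 23 of the 2297 unnamed epithelial cells at 72 h carried 74.0% of the acinar UMIs. The median there was 4.0 UMIs per cell, the same as in chief-like cells. Immediate early and dissociation genes were above control in all 5 classes and 4 DT libraries, with medians relative to all genes from 0.15 in pit-like cells of DT 2 days to 1.59 in parietal-like cells at 36 h. Cells with Xist and no Y-linked UMI were 37.5% of control, 12.1% at 36 h, 30.9% at 48 h, 28.8% at 72 h and 96.9% of DT 2 days.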
